A study of Arabidopsis thaliana with 11 samples.

How the data were processed

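The series holds 11 Affymetrix GeneChip arrays of a custom Arabidopsis design, 1 per RNA sample. Per the labels' protocols, total RNA was isolated with the RNeasy kit from pools of about 24 seedlings, amplified with MessageAmp and labelled with biotin. The deposited values are probe set intensities on a linear scale, some of them below 0, as a subtraction of background leaves; the summarization method, the background correction and any scaling are not given in the sources used here. The array medians of the deposited intensities differed from 9.23 to 22.7, so no normalization between arrays was visible. Groups and lines were taken from the sample titles. The series text calls the replicates biological; nothing names separate growth batches, so the p-values measure the spread between these pools. The series text gives 2 numbers for the second CBF4 line, of which the titles carry 19.

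The table of 19658 probe sets held 19371 plant probe sets, 3 for vector 3′ UTRs, 122 Affymetrix controls and 162 spike controls. The controls were left out of normalization and testing. The plan allowed quantile normalization where arrays are not on a common scale, and this was taken as the main setting. The remaining 19374 probe sets were quantile normalized over the 11 arrays, values under the 20th percentile of all values were raised to it (1.90 intensity units, 0.93 log2), and log2 was taken. Of the plant values 13.4% were below 0 as deposited, and 1487 probe sets were at the floor on all arrays; a difference against a group at the floor understates the change. A probe set counted as at or above the median brightness where the mean of the higher side reached 4.02 log2, the median over all probe sets. Within a line, arrays correlated at r = 0.952 to 0.971, and arrays of different groups at 0.926 to 0.982.

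Gene names came from the platform's annotation table and were matched by gene ID to the RefSeq table of assembly TAIR10.1. Of the plant probe sets 11598 had 1 gene name, 0 had several and 7773 had none; 11547 matched, covering 11320 loci. That annotation names no genome build for the probe sets, so no coordinates are given. Unnamed probe sets are cited by their ID.

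Differences were tested with limma (lmFit and eBayes, two-sided) in a single fit of 5 line groups without a block, which left 6 residual degrees of freedom. The estimate for a construct is the mean of its 2 line coefficients minus wild type. Errors are standard errors of that estimate from the moderated fit. Adjusted p-values are Benjamini-Hochberg over the 19374 probe sets with a threshold of 0.05, and calls are counted over the plant probe sets. Tested comparisons were each construct against wild type, the constructs against each other, each line against wild type and the lines of a construct against each other. Tools were R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15 and matplotlib 3.10.9.

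Before the data were examined, 25 gene lists with 410 loci were fixed, of which 36 were measured under a name, with 1 probe set per gene (the highest mean). The CBF regulon (5 measured), photosynthesis (8) and jasmonate (3) lists were tested with camera at a preset correlation of 0.01 against 11320 genes, with camera at an estimated correlation, and with fry, adjusted over the 3 lists. The remaining 20 measured members sit in 14 lists of 1 or 2, named here by their genes only; the abscisic acid list had 1 measured member and was not tested as a list. A further 38 families of at least 5 genes that share a symbol stem were tested after the data were seen.

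The rule for named genes, set before the data were examined, took in each comparison of constructs up to 10 highest and 10 lowest probe sets with a gene name that passed, had the same direction in both lines and no overlap between the sides, and were at or above the median brightness. Where fewer than 5 passed in a direction, up to 5 with the smallest p that met the other conditions were named. It also took up to 4 members of each list with the smallest p, and up to 3 line differences per direction under the same conditions. After the values were seen this was narrowed: list members whose difference was smaller than its standard error, 37 cases over the 3 comparisons, are counted but not named, except the CBF regulon, whose members are all given. List members at the floor on all arrays were left out. The rule also named the AtNF-YB1 and CBF4 probe sets, which were not found under a name.

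The procedure was tested on simulated data of 19374 probe sets, of which 100 were changed by 1 log2 unit and 100 by 2. All of them were plant probe sets with a mean at or above the median, changed at once. Recovery among dimmer probe sets, or where fewer change, was not measured. It recovered 54%, 57% and 66% of changes of 1 log2 unit, and 91%, 91% and 94% of changes of 2, in AtNF-YB1 against wild type, CBF4 against wild type and CBF4 against AtNF-YB1. False calls made up 10.5%, 11.4% and 6.98% of all calls in a single simulated draw per comparison, above the nominal 5%. The threshold may therefore understate the share of false calls in the real comparisons too, where that share was not measured. Comparisons that share wild type arrays were set against 100 simulated unchanged groups.

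Alternatives changed a single choice each: no scaling or median centring between arrays, no floor with log2(value + 1), a floor at the 40th percentile, dim probe sets left out, probe sets ending in _s_at or _x_at left out, a trended and robust variance, array weights, lines pooled into genotypes (over all arrays, over the genotypes compared, or with line as a random block), the replicate number as a block, and each array left out in turn. Added after the data were seen were the spike controls included, the 25S rRNA signal as a covariate, the same alternatives for the agreement between lines, and the tests of the lists between AtNF-YB1 and wild type without the array labelled wild type replicate 3, with an estimated correlation and by fry.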

Results

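Transcript levels were measured in the shoots of Arabidopsis thaliana seedlings that overexpressed 1 of 2 transcription factors from the constitutive 35S promoter. AtNF-YB1 is a subunit of the CCAAT-binding NF-Y complex, and CBF4 is a member of the CBF/DREB1 group of factors that bind the promoters of cold- and drought-inducible genes. The 11 arrays covered 2 independent lines of each construct, AtNF-YB1 lines 3 and 6 and CBF4 lines 10 and 19, with 2 arrays per line, and 3 arrays of Col-0 wild type. Each array held a pool of about 24 seedlings grown for 14 days on plates under 24 h of light per day, with the shoots separated from the roots. The median probe set intensity as deposited ran from 9.23 to 22.7 between arrays, and 60.3% of the plant probe set values lay above the 95th percentile of the spike control probe sets. The number of arrays limits the precision: 19371 plant probe sets were read with 4 arrays per construct and 3 of wild type.

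Neither AtNF-YB1 nor CBF4 was among the probe sets with a gene name, so the transgenes were followed here through 3 probe sets for the 3′ ends used in plant vectors. An unnamed probe set whose number falls on the CBF4 locus is given with the CBF4 comparison. The NOS 3′ UTR probe set gave 154 to 705 intensity units on the 8 transgenic arrays, against 0.50 and −0.44 on wild type replicates 1 and 2. The array labelled wild type replicate 3 gave 52.3 units of NOS signal. The E9 3′ UTR probe set gave 504 to 591 units on the 4 CBF4 arrays, 2.195 to 112 on the 4 AtNF-YB1 arrays, and 137 and 88.3 on wild type replicates 1 and 2. On the array labelled wild type replicate 3 it gave 1164 units, above every CBF4 array. The NOS difference from wild type was 6.36 ± 1.12 log2 (SE) in the AtNF-YB1 lines and 5.72 ± 1.12 in the CBF4 lines, with limma adjusted p = 0.469 and 0.235, the third wild type array adding to the spread. The CaMV 35S 3′ UTR probe set gave −3.19 to 5.11 units on the transgenic arrays and −2.23 to 1.81 on the wild type arrays, with differences of 0.37 ± 0.24 (adjusted p = 1) and 0.62 ± 0.24 (adjusted p = 0.742). Only NOS told all 8 transgenic arrays from wild type replicates 1 and 2, and the array labelled wild type replicate 3 was not free of vector signal. Counts without it are therefore given below.

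**Figure D1:**
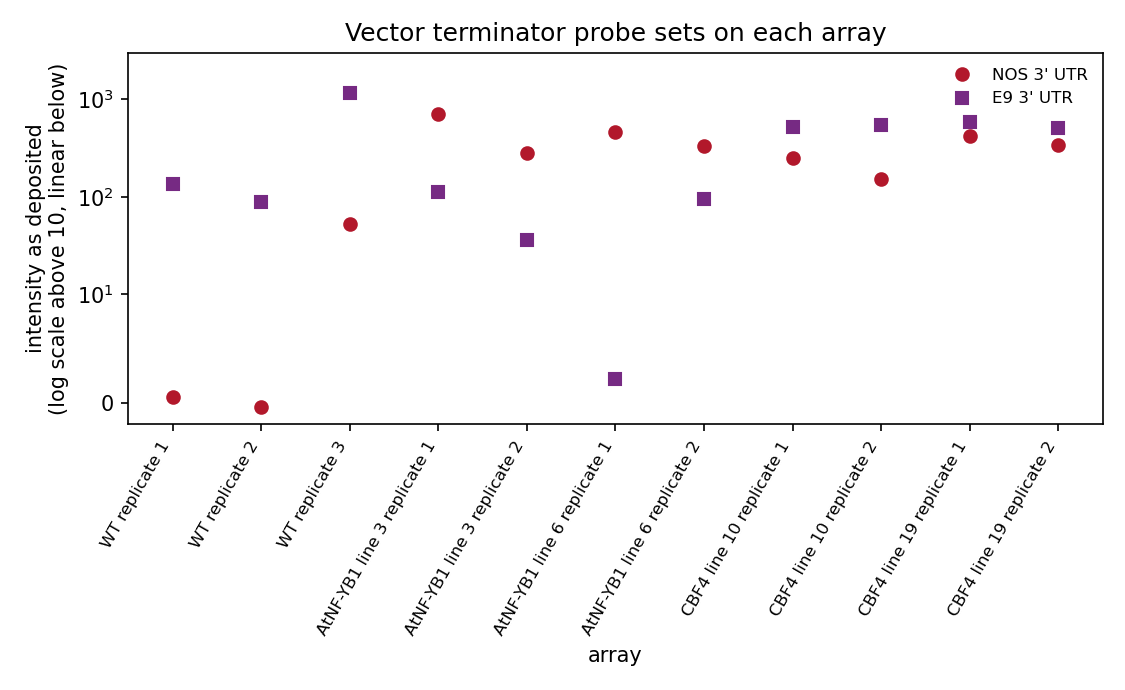
Deposited intensity of the NOS (circles) and E9 (squares) 3′ UTR probe sets on each of the 11 arrays, on an axis that is logarithmic above 10 and linear below. The array labelled wild type replicate 3 shows 52.3 units of NOS and 1164 units of E9 signal, while wild type replicates 1 and 2 show 0.50 and −0.44 units of NOS.

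The comparison of the CBF4 lines with wild type asked which shoot transcripts differ when CBF4 is overexpressed. The cold-regulated genes of the CBF regulon were the largest named change. COR15A, which encodes a chloroplast protein that protects membranes during freezing, rose by 4.56 ± 0.32 log2 (SE, 4 arrays against 3), a 23.7-fold difference (adjusted p = 0.00603). Its neighbour and close copy COR15B rose by 4.81 ± 0.21 and 4.19 ± 0.34 on its 2 probe sets (adjusted p = 0.00162 and 0.0108). KIN1 and KIN2, a pair of small cold- and abscisic acid-inducible proteins, rose by 4.42 ± 0.31 and 2.01 ± 0.10 (adjusted p = 0.00603 and 0.0017). Of 25 alternatives (24 for the first COR15B probe set), the call was lost in 2 for COR15A, 0 and 1 for the COR15B probe sets, 2 for KIN1 and 1 for KIN2. COR15A and COR15B, and KIN1 and KIN2, are similar in sequence, and how far the probe sets share signal was not tested.

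The CBF regulon list held 18 loci, of which 5 were measured under a name, so the rest of the list was not read. Of the 5 measured, 4 rose after adjustment over all probe sets and 5 when adjusted over the list alone. The fifth, the dehydrin COR47, was 1.37 ± 0.19 log2 higher with adjusted p = 0.0815, and passed in 2 of 25 alternatives. The mean difference of the list was 3.31 log2 (camera adjusted p = 3.0e-22, adjusted p = 0.0011 with an estimated correlation, fry adjusted p = 2.36e-06). Outside the list, the sucrose transporter gene SWEET13 rose by 2.05 ± 0.25, and AT1G51090, AT3G55760, AT1G68500 and AT3G17130 rose by 2.76 ± 0.34, 2.40 ± 0.27, 2.12 ± 0.24 and 1.91 ± 0.13. These 5 calls were lost in 17, 15, 11, 13 and 2 of 25 alternatives. Among the probe sets without a gene name, MRT3702_23907C.2_at and MRT3702_810C.2_at were 6.19 ± 0.32 and 5.69 ± 0.57 log2 higher (adjusted p = 0.0017 and 0.0232), larger differences than those of any named gene. These 2 were picked after their values were seen. The C.2 numbers in the probe set IDs of the measured list genes follow locus order. They rise in step with the locus numbers from DFR (AT5G42800, MRT3702_22988C.2_at) over PDF1.2 (AT5G44420, MRT3702_23150C.2_at) and AT5G47590 (MRT3702_23467C.2_at) to UF3GT (AT5G54060, MRT3702_24114C.2_at). At that spacing the number of MRT3702_23907C.2_at falls on the CBF4 locus. For this probe set that argues against a response to CBF4 and for a measure of CBF4 itself, though its sequence was not checked.

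**Figure D2:**
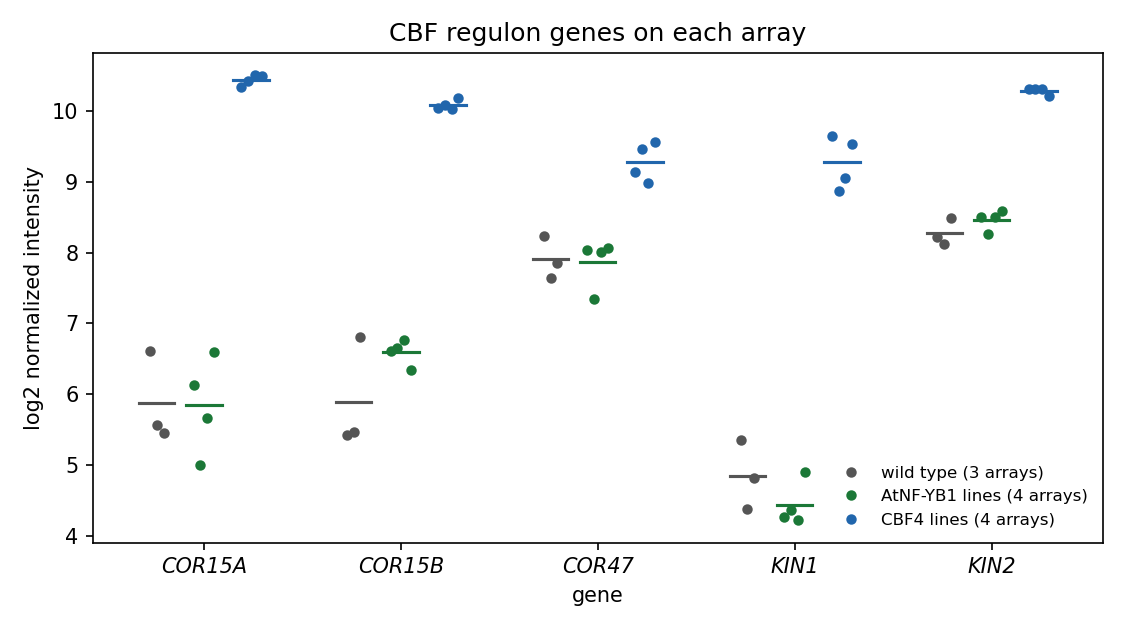
Log2 normalized intensity of the 5 measured CBF regulon genes on each array (points) with the mean of each genotype (bars), for 3 wild type, 4 AtNF-YB1 and 4 CBF4 arrays. The CBF4 arrays lie above all others for each gene, with a COR15A mean of 10.44 against 5.87 in wild type and 5.85 in the AtNF-YB1 lines.

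Fewer named genes were lower in the CBF4 lines. AT3G23550 and AT1G71140, which encode transporters of the MATE efflux family, fell by 1.47 ± 0.16 and 0.77 ± 0.08 log2 (adjusted p = 0.033 and 0.0232). AT3G04210, AT5G35735 and AT1G31550 fell by 1.24 ± 0.15, 0.98 ± 0.12 and 0.72 ± 0.06, and GER2, an enzyme of GDP-L-fucose synthesis, fell by 0.38 ± 0.04 (adjusted p = 0.0282). The calls of these 6 genes, in the order given, were lost in 14, 8, 14, 19, 5 and 14 of 25 alternatives. GER2 was also at −0.30 log2 in the AtNF-YB1 lines, without passing, against the same wild type arrays. Its fall is therefore not shown to be particular to CBF4. The defensin genes PDF1.2b and PDF1.2, markers of jasmonate and ethylene signalling, were −1.86 ± 0.37 and −1.49 ± 0.31 log2 from wild type, with adjusted p = 0.242 and 0.265, and passed in 2 of 24 and 2 of 25 alternatives. Of the 3 jasmonate list members measured 0 passed over all probe sets and 2 passed adjusted over the list alone; the list's camera adjusted p was 0.000373, but adjusted p = 0.0663 with an estimated correlation, and fry gave an adjusted p of 0.023. The PDF1.2 genes are close copies, and cross-hybridization between them was not tested.

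Members of the other lists gave small differences from wild type. The 2 anthocyanin genes DFR and UF3GT were −0.52 ± 0.20 and −0.62 ± 0.21 log2 (adjusted p = 0.766 and 0.632, 2 of 2 passing when adjusted over the list alone), and the stress factor gene WRKY53 was −0.60 ± 0.18 (adjusted p = 0.571, 1 of the 2 members of its list passing when adjusted over the list alone). Adjusted over the 36 members of all lists together 7 passed, with DFR, UF3GT and WRKY53 not among them. DFR and UF3GT were also lower in the AtNF-YB1 lines, at −0.79 and −0.73 log2 from the same wild type arrays. The cytokinin response gene ARR15 was −0.52 ± 0.22, the endoplasmic reticulum folding genes CRT1b and DER1 were −0.28 ± 0.13 and −0.17 ± 0.14, and the salicylate gene SAG101 was −0.31 ± 0.21, none of which passed. The reference gene AT2G28390 was at the floor on every array but CBF4 line 10 replicate 1. Of the 8 photosynthesis genes measured 0 passed. The light-harvesting gene LHB1B2 was 0.09 ± 0.06 higher, and PSBW at 0.07 ± 0.04, SBPASE at 0.09 ± 0.08 and PSAE-1 at −0.06 ± 0.05 changed sign under another scaling of the arrays. The photosynthesis list gave a camera adjusted p of 0.329.

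In all, 45 probe sets differed between the CBF4 lines and wild type at a limma adjusted p below 0.05, 35 higher and 10 lower, of which 31 had a gene name and 34 were at or above the median brightness on the higher side. With these included, 1190 probe sets had an unadjusted p below 0.05, where 969 are expected by chance if every plant probe set could pass. The 1487 probe sets at the floor on all arrays cannot, so that figure is too high. The 2 lines gave 25 calls each, 14 of them higher in both and 3 lower in both, with the wild type arrays shared. Over the 9687 probe sets at or above the median brightness, the differences of the 2 lines correlated at r = 0.713 across probe sets, which are not independent replicates. Simulated unchanged groups sharing the wild type arrays gave a mean of 0.34, from −0.769 to 0.953. The covariance of the 2 lines was 0.07 against 0.0265, a value reached in 11 of 100 draws. The count was 5 (3 higher and 2 lower) on the values as deposited without scaling, and 194 with line as a random block. With the replicate number as a block, given with the processing alternatives below, the count fell. It was 27 without wild type replicate 1, 25 without wild type replicate 2, 31 without the array labelled wild type replicate 3, and 89, 130, 111 and 108 without CBF4 line 10 replicates 1 and 2 and line 19 replicates 1 and 2, the last 4 mostly through dim probe sets (24 to 41 of those calls were at or above the median brightness).

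The comparison of the AtNF-YB1 lines with wild type asked the same of AtNF-YB1. No probe set with a gene name passed the test, the cold-regulated genes among them. COR15A and COR47 were −0.03 ± 0.32 and −0.05 ± 0.19 log2 from wild type, with the opposite sign when each array was centred on its median, KIN1 was −0.41 ± 0.31 and KIN2 was 0.18 ± 0.10. COR15B was 0.69 ± 0.34 and 0.44 ± 0.21 higher on its 2 probe sets (adjusted p = 1 for both). Without the array labelled wild type replicate 3 the differences were 1.15 and 0.71, with adjusted p = 0.0387 and 0.337. Of the 5 CBF regulon members 0 passed, and 0 passed adjusted over the list alone; the list's mean of 0.08 and its median of −0.03 differed in sign (camera adjusted p = 0.435), and the mean was −0.12 on unscaled values. Without the array labelled wild type replicate 3 the mean was 0.14 and the median −0.08, with 2 of 5 members positive, chiefly COR15B. The camera adjusted p was 0.098, adjusted p = 0.616 with an estimated correlation, and the fry adjusted p was 0.0507.

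The named genes with the smallest p-values did not pass. AT3G19120 was 0.45 ± 0.04 log2 higher in the AtNF-YB1 lines (adjusted p = 0.058), higher on 4 of 4 arrays than on any wild type array, and passed in 8 of 25 alternatives, with a lowest adjusted p of 0.00518. AT2G40570, AT1G15170, AT5G18460 and AT3G10720 were 0.74 ± 0.11, 0.50 ± 0.09, 0.39 ± 0.08 and 0.46 ± 0.09 higher (adjusted p = 0.363 to 0.561). AT3G13350 and AT5G47590 were −0.79 ± 0.10 and −0.85 ± 0.17 from wild type (adjusted p = 0.242 and 0.54), the first passing in 2 of 25 alternatives with a lowest adjusted p of 0.027, and GER2 was −0.30 ± 0.04 (adjusted p = 0.275). AT4G22240 and AT3G24670 were −0.19 ± 0.04 and −0.44 ± 0.09 (adjusted p = 0.49 and 0.551). The anthocyanin genes DFR and UF3GT, which act late in pigment synthesis, were −0.79 ± 0.20 and −0.73 ± 0.21 log2 from wild type (adjusted p = 0.861 and 0.99). Adjusted over their list alone 2 of 2 passed, but adjusted over the 36 members of all lists together 0 passed.

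None of the other list members passed either. The defensins PDF1.2b and PDF1.2 were −0.68 ± 0.37 and −0.50 ± 0.31, and the jasmonate list gave a camera adjusted p of 0.145. The DREB-type factor gene tny was −0.32 ± 0.22. CRT1b, RR16, SAG101 and WRKY53 were −0.24 ± 0.13, −0.22 ± 0.21, −0.23 ± 0.21 and −0.23 ± 0.18, the proline gene AT5G38710 was 0.49 ± 0.48 higher, and LHB1B2, LHCB4.2, PSBW and PSAE-1 were 0.10 ± 0.06, 0.10 ± 0.07, 0.07 ± 0.04 and 0.07 ± 0.05 higher, with a camera adjusted p of 0.145 for the photosynthesis list.

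At the same threshold 3 probe sets were called between the AtNF-YB1 lines and wild type, 2 higher and 1 lower. An unadjusted p below 0.05 was reached by 778, fewer than the 969 expected by chance. That figure counts probe sets at the floor on all arrays, which cannot pass, so the shortfall is overstated. None of the 3 probe sets called had a gene name. They were looked at after their values were seen. The lower, MRT3702_25024C.2_at, fell by 0.89 ± 0.06 log2 with all 4 AtNF-YB1 arrays below all 3 wild type arrays. The higher pair, MRT3702_17045C.2_at and MRT3702_11388C.2_at, lay near the floor and was raised in line 3 alone. With the arrays centred on their medians the split was 3 higher and 0 lower. No call was left on unscaled values, without a floor, with dim probe sets left out, or with the replicate number as a block. The count was 1 with the lines pooled or with the 25S rRNA covariate, 5 with a higher floor, a trended variance or array weights, and 19 with line as a random block. The count was 5, 6 and 10 without wild type replicates 1, 2 and the array labelled 3, 166 and 57 without AtNF-YB1 line 3 replicates 1 and 2, 69 and 54 without line 6 replicates 2 and 1, and 10 without either CBF4 line 10 array, with 0 to 9 calls at or above the median brightness.

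Line 3 alone gave 5 calls and line 6 gave 0, with 828 and 687 probe sets at an unadjusted p below 0.05. The differences of the 2 AtNF-YB1 lines correlated at r = 0.372 across probe sets. Simulated unchanged groups gave a mean of 0.399, from −0.854 to 0.964. Their covariance was 0.0236 against a simulated mean of 0.0276. In simulated data of the same size the test recovered 54 of 100 probe sets changed by 1 log2 unit and 91 of 100 changed by 2 between these groups. The simulated changes were all at or above the median brightness and were made together, which gave 162 calls. With 3 calls in the real comparison the adjusted threshold is stricter, so the share of real changes missed was not measured.

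The direct comparison of the 2 constructs, which does not use the wild type arrays as a reference, asked where the responses differ. The CBF regulon was again the largest named difference. KIN1, COR15A and KIN2 were higher in the CBF4 lines by 4.83 ± 0.29, 4.59 ± 0.29 and 1.83 ± 0.09 log2 (4 arrays against 4, adjusted p = 0.00229, 0.00315 and 0.00131), and COR15B by 4.37 ± 0.20 and 3.49 ± 0.31 on its 2 probe sets. Of 25 alternatives 1 ended the call of KIN2 and 1 that of the second COR15B probe set. COR47 was higher by 1.42 ± 0.18 (adjusted p = 0.0409), a call lost in 14 of 25 alternatives. With it 5 of the 5 measured members passed, over all probe sets and adjusted over the list alone (mean 3.23 log2, camera adjusted p = 6.68e-20, adjusted p = 0.00152 with an estimated correlation). AT1G51090, AT1G68500, AT3G55760 and SWEET13 were higher by 3.01 ± 0.31, 2.36 ± 0.23, 2.15 ± 0.25 and 2.12 ± 0.23, and AT3G28220 by 1.85 ± 0.22 (adjusted p = 0.033). These 5 calls were lost in 4, 2, 9, 12 and 11 of 25 alternatives.

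Lower in the CBF4 than in the AtNF-YB1 lines were AT3G20340 at −2.84 ± 0.27 log2 (adjusted p = 0.0153) and HIS1-3, a linker histone gene induced by drought, at −1.75 ± 0.17 (adjusted p = 0.0153). Both were dim in the CBF4 lines, with means of 1.48 and 2.79 log2 where the floor was 0.93, so the size of these differences is uncertain: over the alternatives they ran from −3.02 to −1.09 and from −1.85 to −1.31, and the calls were lost in 4 and 3 of 24. The MATE transporter genes AT3G23550, AT1G15170 and AT1G71140 were at −1.37 ± 0.15, −1.001 ± 0.086 and −0.92 ± 0.07 (adjusted p = 0.0258, 0.0117 and 0.00753), with calls lost in 7, 1 and 2 of 25 alternatives. APS3, an ATP sulfurylase of sulfate assimilation, was at −0.77 ± 0.10 (adjusted p = 0.0422), and AT1G71970 and AT1G31550 were at −0.71 ± 0.08 and −0.56 ± 0.05. These 3 calls were lost in 12, 14 and 5 of 25 alternatives. PDF1.2b and PDF1.2 were at −1.18 ± 0.34 and −0.99 ± 0.29 and did not pass; the jasmonate list gave a camera adjusted p of 0.00424, but adjusted p = 0.126 with an estimated correlation, and fry gave an adjusted p of 0.0493, with 2 of 3 members passing adjusted over the list alone.

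The remaining list members gave no call between the constructs. The root markers PYK10 and EXPA7 were −0.44 ± 0.31 and −0.59 ± 0.52, WRKY53 was −0.37 ± 0.17, ARR15 was −0.46 ± 0.21 and DER1 was −0.27 ± 0.13 log2. CML38 was −0.61 ± 0.55 through AtNF-YB1 line 3 replicate 2 alone, all other arrays of both constructs being at the floor, and 0 without it. AT5G38710 was −0.82 ± 0.45, and −0.28 without CBF4 line 10 replicate 1, where it was at the floor. The gene tny was 0.47 ± 0.21 and DFR 0.27 ± 0.19 higher, AT2G28390 was 0.58 ± 0.45 higher through a single array, and PSAE-1 was −0.13 ± 0.04 with adjusted p = 0.476; the photosynthesis list gave a camera adjusted p of 0.535.

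Between the constructs 60 probe sets were called by limma, 41 higher and 19 lower in the CBF4 lines, 45 of them at or above the median brightness and 38 with a gene name, and 1544 had an unadjusted p below 0.05. The count was 9 on unscaled values, 141 with line as a random block and 59 without the array labelled wild type replicate 3. It fell with the replicate number as a block, given with the processing alternatives below. Without AtNF-YB1 line 3 replicates 1 and 2 it was 240 (61 higher and 179 lower) and 96 (33 and 63), without line 6 replicates 1 and 2 it was 116 (41 and 75) and 129 (42 and 87), and without CBF4 line 10 replicates 1 and 2 and line 19 replicates 1 and 2 it was 117, 159, 113 and 132.

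By limma 0 probe sets were called in both comparisons with wild type. The differences of the 2 constructs from wild type correlated at r = 0.319 across probe sets. Simulated unchanged groups against the same wild type arrays gave a mean of 0.523, from −0.643 to 0.949, and the covariance was 0.0193 against 0.0275, so the correlation did not exceed what shared controls give.

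Within each construct the 2 lines differed at few probe sets, all of them below the median brightness, so no gene met the conditions for naming; those given here were picked after their values were seen. AtNF-YB1 line 6 was higher than line 3 for AT1G12290 by 1.18 log2 and for AT3G56930 by 0.88, and lower for AT1G13520 (−1.34) and for the unnamed MRT3702_17045C.2_at and MRT3702_11388C.2_at, which makes 5 calls with 809 at an unadjusted p below 0.05. CBF4 line 19 was higher than line 10 for AT5G23950 by 1.97 and for AT1G48070 by 1.56, and lower for AT1G47480 (−1.72), which makes 3 calls with 663 at an unadjusted p below 0.05. The CBF regulon genes COR15A and KIN1 gave like values in both CBF4 lines, 4.55 and 4.58 and 4.49 and 4.35 log2 above wild type in lines 10 and 19. COR47 was lower on both line 10 arrays (9.13 and 8.98 log2) than on both line 19 arrays (9.46 and 9.56). No measured CBF regulon gene was called between the lines. The 5 and 3 calls between lines fell to 1 and 0 on unscaled values and to 0 and 0 with dim probe sets left out. The 809 and 663 are below the 969 expected by chance, a figure too high because it counts probe sets always at the floor.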

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

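The tests of other splits of the arrays were set before the results were seen; those of the vector signal and of the first principal component were chosen only afterwards.

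The array labelled wild type replicate 3 carried vector signal, which the comparisons of plant genes do not use. Its NOS 3′ UTR signal was 52.3 units, against −0.44 and 0.50 on the other wild type arrays, and its E9 3′ UTR signal was 1164 units, against 88.3 and 137. A CBF4 array under a wrong label is argued against by the CBF regulon, whose median difference between this array and the other wild type arrays was −0.0473 log2 (SD 0.74), where the CBF4 difference was 4.35. On quantile-normalized log2 values its E9 signal was 0.49 above the highest CBF4 array (SD 0.15), which argues against CBF4 RNA mixed into the sample. On that scale E9 was 3.06 above the highest AtNF-YB1 array (SD 2.74). This margin is only a little over that spread, which AtNF-YB1 line 6 replicate 1 widens (0.98, near the floor). NOS on this array was 5.44, below the 8.57 to 9.31 of the AtNF-YB1 arrays. Both argue against an AtNF-YB1 array under a wrong label. RNA of a plant with another construct stays open and was not tested, and no biological explanation was tested.

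Arrays of the same line lay apart along the first principal component, which held 30.1% of the variance: CBF4 line 10 replicates 1 and 2 scored 25.9 and −6.50, and AtNF-YB1 line 6 replicates 2 and 1 scored 9.23 and −12.7. Over the 11 arrays the score followed the log2 25S rRNA signal (r = 0.725, permutation p = 0.0128, adjusted over 3 relations 0.0192; r = 0.712 without the 2 farthest arrays). It also followed the GAPDH 3′ to 5′ ratio, a measure of RNA degradation (r = −0.748, permutation p = 0.00749, adjusted 0.0192), less firmly by rank (rho = −0.600, permutation p = 0.0575) and without the 2 farthest arrays (r = −0.452). Array brightness before normalization gave r = 0.204 (permutation p = 0.553), and −0.303 without the 2 farthest arrays. This cannot exclude a relation with so few arrays. The arrays left out include the dimmest, AtNF-YB1 line 3 replicate 2, which had the lowest score (−25.3). Ribosomal RNA carried into the labelled RNA, RNA degradation and array brightness all stay open as sources of this spread, and no biological explanation was tested.

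Other splits of the same arrays were counted with the lines pooled. For AtNF-YB1 against wild type, 23 of 35 splits gave at least the 1 call of the true grouping, and the highest other split gave 11, so the count cannot be told from chance. For CBF4 against wild type 1 of 35 splits, the true grouping with 35 calls, reached its count, the next giving 21, and for CBF4 against AtNF-YB1 1 of 35, the true grouping with 57 calls, the next giving 5.

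Tests of the difference between related groups gave calls in 3 comparisons: 60 probe sets between the constructs, 5 between the AtNF-YB1 lines and 3 between the CBF4 lines. The last 2 counts were 1 and 0 on unscaled values and 0 and 0 with dim probe sets left out. Beside them 809 and 663 probe sets had an unadjusted p below 0.05. Chance gives 969 if probe sets always at the floor, which cannot pass, are counted.

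Single arrays lay far from the other arrays of their construct, relative to the range of the 4, in 10 of 102 groups of 4 tested. Chance gives about 1 in 20, or 5.1. That rate does not hold where 3 of the 4 values tie, as for CML38, AT2G28390 and KIN2, since any departure then passes. On AtNF-YB1 line 3 replicate 2, APS3 was at 6.65 log2 (others 6.84 to 6.86) and CML38 at 3.36 (others at the floor, 0.93). On AtNF-YB1 line 6 replicate 1, COR47 was at 7.34 (others 8.01 to 8.07), and on line 6 replicate 2 the 25S rRNA signal was 424 units (others 78.0 to 100). On CBF4 line 10 replicate 1, AT1G71140 was at 4.19 (others 4.30 to 4.31), AT2G28390 at 3.23 (others at the floor) and AT5G38710 at 0.93 (others 2.82 to 3.11). On CBF4 line 19 replicate 2, KIN2 was at 10.21 (others 10.31), UF3GT at 4.1005 (others 4.78 to 4.88) and the median intensity at 12.9 units (others 17.5 to 18.1).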

How the results depend on the processing

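The inclusion of the spike controls, the 25S rRNA covariate, the list tests by estimated correlation and fry without the array labelled wild type replicate 3, and all alternatives for the agreement between lines were chosen only after the data were seen; the others were planned. The 35 cases of a named gene past the threshold kept their direction in all 871 alternatives and their call in 631, with 240 calls lost; SWEET13 and AT5G35735 in CBF4 against wild type lost theirs in 17 and 19 of 25, and COR47 between the constructs in 14 of 25. Of 1401 alternatives for the 57 cases not past it, 1370 kept side and direction, 20 gained a call and 11 reversed. The 37 cases of a list member within 1 SE gained no call in 902 alternatives, and 70 reversed. Below, N, C and D stand for AtNF-YB1 against wild type, CBF4 against wild type and CBF4 against AtNF-YB1, with main counts of 3, 45 and 60; where no reason is given, the cause was not tested. Weak signal may limit all counts, which was not tested: 13.4% of plant values were below 0 as deposited. The floor at the 20th percentile holds 20.0% of values by its definition.

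On values as deposited, with no scaling between arrays, the counts were 0 (N), 5 (C) and 9 (D), 0 for AtNF-YB1 line 3, 1 for line 6, 1 for CBF4 line 10, 0 for line 19, and 1 and 0 between the lines of AtNF-YB1 and CBF4; the median of all probe sets was off by −0.167, −0.0989 and 0.0317 log2 in N, C and D. The CBF regulon mean in N was −0.12, and in C PSBW was −0.0554 and SBPASE −0.0346. With each array centred on its median, COR15A and COR47 in N were 0.0226 and 0.0311, PSAE-1 in C was 0.0156, and CBF4 line 10 had 16 calls. Without a floor N had 0 and line 6 had 1. With the floor at the 40th percentile N had 5, line 3 had 9, and the line differences 8 (AtNF-YB1) and 7 (CBF4).

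With dim probe sets left out, so that fewer were tested, N had 0, line 3 had 0, line 10 had 38, line 19 had 39, and both line differences 0. Without _s_at and _x_at probe sets the AtNF-YB1 lines differed at 3. A trended and robust variance and array weights each gave 5 in N, pooling the lines over all arrays or over the 2 genotypes gave 1 each, and the 25S rRNA covariate gave 1. With line as a random block, at a consensus correlation of −0.219, N, C and D had 19, 194 and 141 calls; a negative correlation shrinks the errors, and camera was not run there. The abscisic acid list, with 1 measured member, was not run through camera.

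With the replicate number as a replicate block the counts were 0 (N), 13 (C), 21 (D), 1 (line 3), 10 (line 10), 9 (line 19), and 1 and 0 between the lines, with r = 0.475 between the constructs and 0.513 between the AtNF-YB1 lines. The block absorbs the array labelled wild type replicate 3, the sole replicate 3. Of 20 pairs of arrays with the same number 7 correlated above 0.1 and 11 below 0, and 5 of 10 arrays fitted best with their own number. Residuals of the 2 arrays of a line mirror each other, so each pair of transgenic lines counts the same r 2 times. AtNF-YB1 line 3 with CBF4 lines 10 and 19, and those CBF4 lines with each other, gave 0.414, 0.124 and 0.341. AtNF-YB1 line 6 gave −0.165, −0.469 and −0.254 with lines 3, 10 and 19. The tally therefore cannot decide whether the numbers mark pairs.

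Leaving out each array in turn gave 2 to 166 calls in N, 25 to 130 in C, 43 to 240 in D, 4 to 210 for line 3, 0 to 86 for line 6, 12 to 120 for line 10, 16 to 109 for line 19, 3 to 208 between the AtNF-YB1 lines and 0 to 98 between the CBF4 lines. Of these 0 to 9, 20 to 41 and 28 to 62 in N, C and D were at or above the median brightness. A line left with 1 array was assumed to vary like the other groups. In N the CBF regulon mean ran from −0.0862 to 0.178, COR15A from −0.239 to 0.336, COR47 from −0.217 to 0.115 and WRKY53 from −0.368 to 0.00297. The correlation between the constructs ran from 0.212 to 0.475, and that between lines from 0.105 to 0.513 (AtNF-YB1) and from 0.502 to 0.766 (CBF4).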

Other observations

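The families described here were chosen after the data were seen; of the 3 tests of their pattern, that of signal shared within a family was set before its result was seen, and those of the array labelled wild type replicate 3 and of the 25S rRNA signal only afterwards.

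Among 38 gene families 4 passed as groups lower in the CBF4 lines than in wild type by camera at its preset correlation, with adjusted p of 0.000206 for JAL and for PDF, 0.000262 for CYP71B and 0.00961 for MSRB. None of the 4 passed with an estimated correlation (adjusted p = 0.537, 0.589, 0.365 and 0.537) or by fry (adjusted p = 0.25, 0.303, 0.217 and 0.303), and 0 of their members passed over all probe sets. The 5 jacalin-related lectin genes measured were all negative, with JAL23 at −1.10 ± 0.25 and JAL31 at −0.78 ± 0.33 log2 and a median of −0.62. The defensin genes PDF1.2, PDF1.2b, PDF1.2c and PDF1.3, which respond to jasmonate and ethylene, were at −1.49 ± 0.31, −1.86 ± 0.37, −1.86 ± 0.40 and −1.81 ± 0.38, while PDF1A and PDF1B, peptide deformylases that share only the symbol, were at 0.05 ± 0.12 and −0.07 ± 0.13, and PDF1.5 was at 0.18 ± 0.72. The test of the PDF family and the medians over all families below include these 3. Of the 19 CYP71B cytochrome P450 genes 18 were at or below 0 (median −0.23), and of the 5 methionine sulfoxide reductase genes (median −0.28, highest −0.14) MSRB6 was at −0.55 ± 0.13 and MSRB4 at −0.79 ± 0.34.

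Over the 36 members of these families the median was −0.38 log2 (quartiles −0.75 and −0.07), −0.42 on unscaled values and −0.35 with the arrays centred on their medians. Without probe sets marked as shared the median of 29 members was −0.27 (quartiles −0.62 and −0.07). This cannot decide whether signal is shared within a family. With 33 of 36 members at or below 0 at the start, leaving out these few could not lift the upper quartile above 0. The array labelled wild type replicate 3 is argued against as the whole cause by −0.43 without it (quartiles −0.91 and −0.17), and the 25S rRNA signal by −0.39 with it as a covariate (quartiles −0.76 and −0.09). The pooled medians rest most on the 19 CYP71B genes and say little about the smaller families. A response of these families to CBF4 stays open as a hypothesis, found and tested on the same data, and the loss of the calls with an estimated correlation and by fry leaves open that few independent signals underlie it.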
